A study of Mus musculus with 6 samples.

How the data were processed

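Transcript levels were measured on 6 whole-transcript arrays hybridised with biotin-labelled material from sorted haematopoietic stem cells of C57BL/6J mice. Each array held 1 pool, made from the marrow of 20 mice, and the pools were sorted as CCR2-negative or CCR2-positive, with 3 pools of each kind that the design calls biological replicates. Total RNA was isolated with a kit for small cell numbers, and 5 ng of it per pool was amplified before labelling, per the labels' protocols. The other surface markers of the sort, and whether a CCR2-positive and a CCR2-negative pool came from the same mice, are not given in the sources used here.

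The authors deposited 1 table of log2 values, with 41345 probe sets in rows and the 6 arrays in columns. Per the submitters' processing notes the values come from RMA, which corrects the background, equalises the distributions of the arrays and summarises the probes of a probe set. Its version and settings are not given in the sources used here, and neither are detection calls or the scanner's raw intensities. That the deposited values are on a log2 scale was checked from their range, 2.39 to 13.3 over all arrays, with medians of 5.48 to 5.58 per array. No column belonged to a sample outside the 6. Equalising the distributions removes most of a difference in total signal between pools, so that changes are relative to the other genes of the same array. The deposited distributions still differed, as the array medians show. The amplification of nanogram amounts adds spread between pools that cannot be separated here from that of the animals. Signal over background is unknown for each probe set, and the number of arrays sets the precision. The median standard error of a log2 difference was 0.127, and the median reach of its 95% interval was 0.289 to either side.

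Gene names came from the platform annotation: 23521 probe sets had 1 gene, 1814 had several and were left unnamed, and 16010 had none listed. Of the probe sets with 1 gene, 23328 were matched by gene number to a table of mouse RefSeq genes of assembly GRCm38.p6, and no symbol needed an update. Where a gene had several probe sets (1082 genes), the one with the highest mean over all 6 arrays was used, which left 22180 genes. List members without a probe set of their own in this annotation, among them the alpha and beta globin genes, were not analysed here.

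The CCR2-positive pools were compared with the CCR2-negative pools with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no other covariate), and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The same fit was made on all probe sets. Before the data were examined, 28 gene lists were fixed: progenitor and lineage genes, markers of other marrow cells, cell cycle, metabolism, interferon, innate signalling, handling stress and sex-linked genes. Of their 602 symbols, 551 were measured, 4 of them under an older name. Ccr2, which defines the sort, was in no list. The 27 lists with at least 5 measured genes were tested against all other genes with camera at a preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation, camera on ranks and fry were alternatives. Each list's members were also adjusted over the list alone, and each list's median was placed among those of 10000 random lists of the same size matched on mean level. The members of a random list were drawn independently, so for lists of correlated members these percentiles are too extreme.

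The genes named in the report were set by a rule fixed together with the lists. It takes Ccr2, Cbfa2t3, the genes with the largest differences past the threshold, or, where fewer than 6 pass in a direction, the 6 with the smallest unadjusted p whose pools do not overlap, and up to 4 members of each list with the smallest p. All members of the surface marker and sex-linked lists may be named. Predicted genes, RIKEN clones and small RNA entries were passed over (1 among the higher and 2 among the lower genes).

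The limma fit was tested on data simulated for this comparison from the measured means and spreads of the 22180 genes, in 10 simulations with 200 changed genes each. It recovered 74.3% of the genes changed by 1 on the log2 scale, 96.7% at 2 and 99.7% at 3, with 3.73% to 5.00% of the calls false. With independent simulated noise, camera called a list shifted by -0.4 in 10 of 10 simulations and none of 210 unshifted lists. The limma simulations used independent noise as well. In the data the estimated correlation between members was 0.472 for stem cell identity and 0.534 for erythroid genes, so these rates of false calls need not carry over. Alternatives were a filter on dim probe sets at the 25th percentile or the median, a second quantile normalization, median centring, the replicate number as a block, eBayes with trend and robust settings, array weights, the mean of a gene's probe sets, each pool left out in turn, and other thresholds. Cyclic loess between arrays was added after seeing the data. The labels state no pairing, so the replicate numbers were not treated as pairs. Pools that share a number deviated from their group means with r = 0.025 to 0.045, which with 3 pools per group cannot exclude pairing.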

Results

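Haematopoietic stem cells that carry the chemokine receptor CCR2 were compared with those that lack it. CCR2 is the receptor for CCL2 and guides monocytes out of the marrow. The arrays profiled 3 CCR2-positive and 3 CCR2-negative pools of sorted mouse stem cells, each from 20 mice. Arrays within the CCR2-negative group correlated at r = 0.975 to 0.983 across probe sets, which are not independent replicates. Within the CCR2-positive group r was 0.966 to 0.974, and between the groups it was 0.960 to 0.977. CCR2-positive replicates 1 and 2 had a mean r of 0.9717 and 0.9701 with their own group and of 0.9724 and 0.9719 with the other. CCR2-positive replicate 3 had the lowest mean r of all pools, 0.968 with its own group and 0.965 with the other. The median SD between pools was 0.129 on the log2 scale for CCR2-negative and 0.150 for CCR2-positive pools. Below, a difference is the mean log2 value of the CCR2-positive pools minus that of the CCR2-negative pools, given with its standard error.

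The Ccr2 transcript was measured first, because it bears on the sort. Its log2 value was 6.70 ± 0.47 (SD, n = 3) in the CCR2-positive pools and 5.91 ± 0.32 (SD, n = 3) in the CCR2-negative pools, a 1.73-fold difference. The difference of 0.79 ± 0.24 had a 95% interval of 0.23 to 1.35. It had an unadjusted limma p of 0.0111 and an adjusted p of 0.274, so it did not pass the threshold over all genes. The pools also overlapped: CCR2-positive replicate 3 had 6.18 and CCR2-negative replicate 2 had 6.26.

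**Figure D1:**
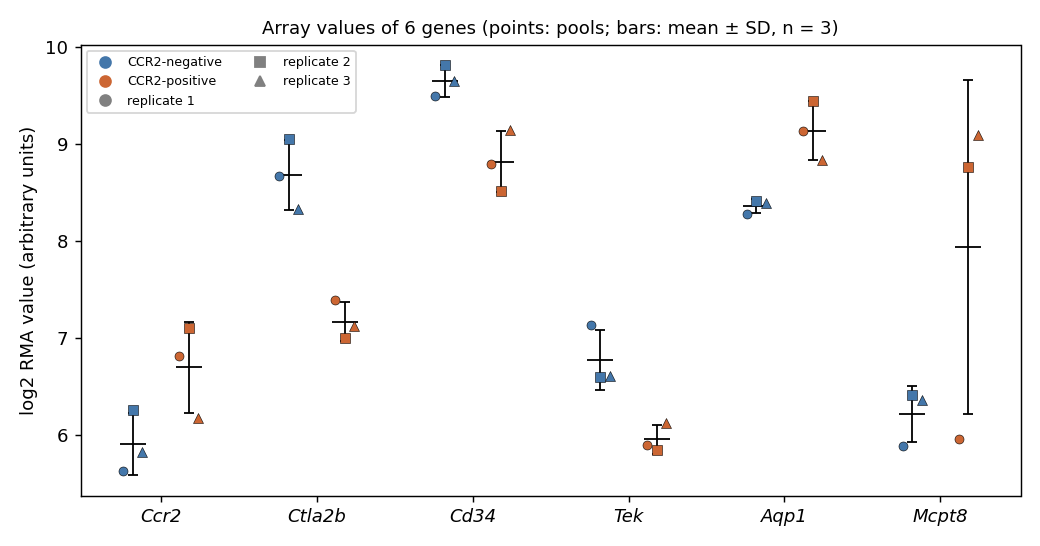
Log2 RMA values (arbitrary units) of 6 genes in each pool, by sort and replicate number, with the mean ± SD of 3 pools as bars. Ctla2b, Cd34 and Tek are lower in all 3 CCR2-positive pools, Aqp1 is higher in all 3, Ccr2 overlaps between the groups, and Mcpt8 is high in 2 of the 3 CCR2-positive pools.

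No gene passed an adjusted p of 0.05 in the limma fit over 22180 genes, and the smallest adjusted p was 0.177. At an unadjusted p under 0.05 there were 2716 genes, against 1109 that chance alone would give, of which 1249 were higher and 1467 lower in CCR2-positive pools. This balance turned with the scaling, to 1463 higher and 1227 lower after a second quantile normalization, while median centring gave 1027 higher and 1621 lower. The pools of the groups did not overlap for 18.6% of the genes, where chance gives 10%, with 2389 of these genes higher and 1747 lower. At an adjusted p under 0.2 there were 318 genes, 74 of them higher and 244 lower. Ctla2b, which encodes a cysteine protease inhibitor-like protein, was 2.85-fold lower (difference -1.51 ± 0.19). Cyp4v3, a cytochrome P450, was 2.60-fold lower (-1.38 ± 0.20). Zfp945, a zinc finger gene, differed by -0.93 ± 0.13 and Cep68, a centrosomal protein gene, by -0.89 ± 0.12. Ddx5, an RNA helicase, differed by -0.84 ± 0.11 and Sox4, a transcription factor gene, by -0.75 ± 0.11. In the other direction, Atp1b2, a subunit of the sodium-potassium pump, was 1.99-fold higher (0.99 ± 0.18). The expressed sequence AI839979 differed by 0.90 ± 0.15, Slc22a23, a transporter gene, by 0.67 ± 0.11, and Cd248, which encodes endosialin, by 0.63 ± 0.11. Clec7a, the beta-glucan receptor dectin-1 of myeloid cells, differed by 0.57 ± 0.10, and Mefv, which encodes pyrin, by 0.51 ± 0.10. All 12 had the same adjusted p of 0.177. They were picked by the smallest unadjusted p among genes whose pools did not overlap, so their lack of overlap is not a result. On all 41345 probe sets no probe set passed either (smallest adjusted p = 0.314), with 4410 at an unadjusted p under 0.05.

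Genes of stem cell identity were lower in the CCR2-positive pools. Of 24 measured members of this list, 22 were lower and 2 higher, with a median difference of -0.39. The members varied together (estimated correlation 0.472), so they are not 24 separate pieces of evidence. Tek, the receptor of angiopoietin, was 1.76-fold lower (-0.82 ± 0.16), and Krt18, a keratin gene, was 1.80-fold lower (-0.85 ± 0.22). Hlf, a transcription factor of stem cells, differed by -0.66 ± 0.17 and Hoxb5, a marker of long-term stem cells, by -0.47 ± 0.11. These 4 and 3 further members passed when adjusted over the list alone, and 0 passed over all genes. The mean of the list was 7.05 ± 0.25 (SD, n = 3) in CCR2-positive and 7.45 ± 0.19 (SD, n = 3) in CCR2-negative pools. The difference of the list mean was -0.40 ± 0.18 over the pools. The nearest pools were CCR2-positive replicate 3 at 7.26 and CCR2-negative replicate 3 at 7.30. Camera called the list lower at the preset correlation (adjusted p = 2.4e-09), but not with an estimated correlation (adjusted p = 0.389). Without CCR2-positive replicate 2 the median was -0.24 and the preset call stood (adjusted p = 6.1e-05).

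Surface markers used to gate stem and progenitor cells were lower in 9 of 11 cases, with a median of -0.32. The list mixes markers of stem cells with markers of progenitors, so its median is not a second measure of stem cell identity. This list shares 3 genes with the stem cell identity list. Cd34, which encodes a sialomucin used to divide stem and progenitor cells, was 1.78-fold lower (-0.83 ± 0.17), and Cd27, a receptor of the TNF family, was 1.52-fold lower (-0.61 ± 0.15). Both passed when adjusted over the list alone, and 0 members passed over all genes. Procr differed by -0.37 ± 0.13, Kit, the receptor of stem cell factor, by -0.32 ± 0.13, Slamf1 by -0.35 ± 0.21 and Esam by -0.49 ± 0.32. Cd48, absent from the most primitive stem cells, differed by 0.33 ± 0.22, and Flt3 by 0.01 ± 0.13, which turned to -0.0126 with median centring and -0.0121 with cyclic loess. The differences of Il7r (-0.06 ± 0.10), Cd244a (-0.13 ± 0.13) and Itga2b (-0.06 ± 0.15) were about the size of their standard errors or smaller. That of Itga2b turned to 0.0077 after a second quantile normalization. Il7r had low means, 3.63 and 3.69 with CCR2-positive first, under those of the Y-linked genes given below. Camera gave an adjusted p of 0.0028 at the preset correlation, and an adjusted p = 0.389 with an estimated correlation. Without CCR2-positive replicate 2 the median was -0.10, with an adjusted p of 0.0238.

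Erythroid genes were higher in the CCR2-positive pools, all 19 measured members, by a median of 0.47. Rhag, which encodes the Rh-associated glycoprotein, was 2.12-fold higher (1.09 ± 0.33), and Tspo2, a gene of maturing erythroid cells, was 1.89-fold higher (0.92 ± 0.28). Aqp1, the water channel of red cells, was 1.71-fold higher (0.78 ± 0.15) and Epor, the erythropoietin receptor, 1.42-fold higher (0.51 ± 0.15). Of the list, 8 members passed when adjusted over the list alone, these 4 among them, and 0 passed over all genes. The list mean was 8.75 ± 0.25 (SD, n = 3) against 8.23 ± 0.23 (SD, n = 3), a difference of 0.52 ± 0.19 over the pools. Camera gave an adjusted p of 2.0e-09 at the preset correlation and an adjusted p = 0.389 with an estimated correlation, which was 0.534 between members of this list. The preset call held without any 1 pool, with medians from 0.35 to 0.62. Across the pools the erythroid and stem cell identity means ran nearly opposite, so they are not separate results. From their means over all pools they lay at -0.52 and 0.41 in CCR2-negative replicate 1, and at 0.53 and -0.47 in CCR2-positive replicate 2.

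Markers of mature myeloid cells were also higher. In the monocyte and macrophage list 22 of 25 members were higher, with a median of 0.24, and in the mature neutrophil list 18 of 20, with a median of 0.21. The list means of the groups overlapped. For monocyte genes CCR2-positive replicate 3 had 6.18 and CCR2-negative replicate 2 had 6.22, and for neutrophil genes 5.39 and 5.40. Lgals3, which encodes galectin-3, was 1.41-fold higher (0.50 ± 0.11) and passed when adjusted over the list alone, as the single member of either list to do so, and 0 passed over all genes. F13a1, a coagulation factor gene of monocytes, differed by 0.66 ± 0.18, Adgre1, which encodes a macrophage surface receptor, by 0.38 ± 0.15 and Ms4a6d by 0.30 ± 0.14. Ms4a6d had low means, 4.12 and 3.81 with CCR2-positive first, in the range of the Y-linked genes given below. Among neutrophil genes Lcn2, a siderophore-binding protein gene, differed by 0.58 ± 0.14, and the granule protein genes Ngp and Chil3 by 0.62 ± 0.22 and 0.60 ± 0.24. Itgam, which encodes CD11b, differed by 0.47 ± 0.16. Camera called both lists higher at the preset correlation (adjusted p = 0.0028 and 0.0073), and neither with an estimated correlation (adjusted p = 0.389 for both). Both calls were lost without CCR2-positive replicate 2, where the medians were 0.11 for monocyte genes (adjusted p = 0.0929) and 0.13 for neutrophil genes (adjusted p = 0.130). The neutrophil median was 0.34 among the members left without the probe sets under the 25th percentile of level, and 0.47 without those under the median level (adjusted p = 0.0050 and 0.0015). In CCR2-positive replicate 2 the list means lay 0.38 and 0.42 above their means over the 6 pools, its stem cell identity mean lay -0.47 from its own, and its erythroid mean 0.53 above.

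**Figure D2:**
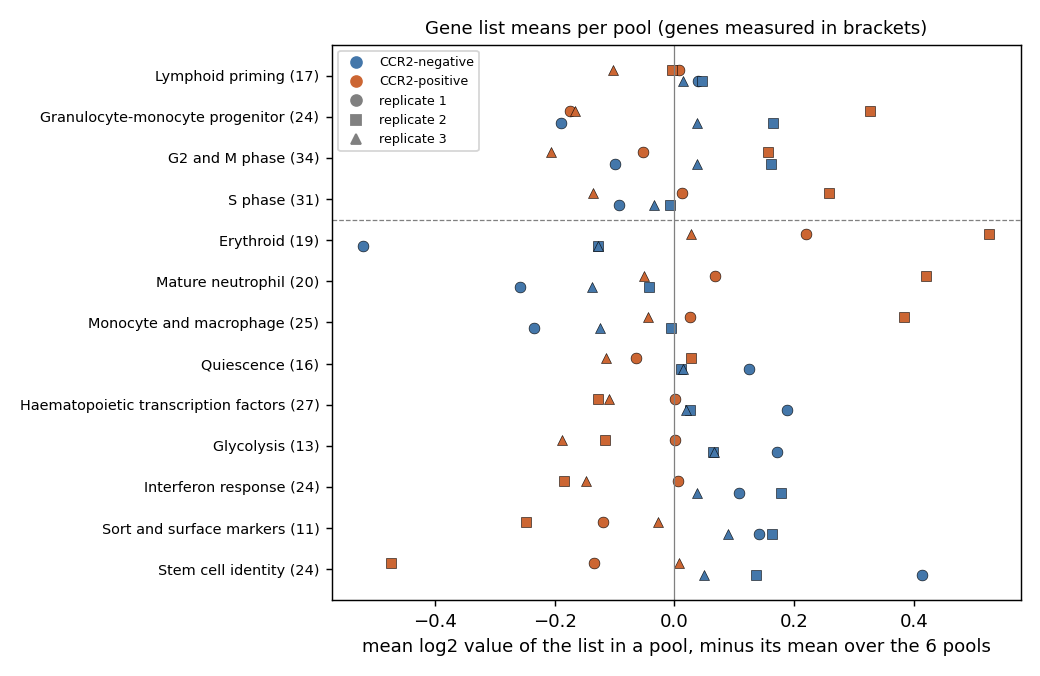
Mean log2 value of each gene list in each pool, relative to the list's mean over the 6 pools, for the 9 lists called by camera at the preset correlation (under the dashed line) and 4 lists that were not. CCR2-positive replicate 2 lies at -0.47 for stem cell identity and at 0.53 for erythroid genes, and CCR2-negative replicate 1 lies at the opposite ends, 0.41 and -0.52.

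Interferon-induced genes were lower, 19 of 24 members, with a median of -0.23. Rtp4, a transmembrane protein gene, was 1.91-fold lower (-0.94 ± 0.22) and Igtp, an interferon-induced GTPase gene, was 1.52-fold lower (-0.60 ± 0.14), and both passed when adjusted over the list alone. Iigp1, another such GTPase, differed by -0.55 ± 0.17 and Ifitm3, which restricts the entry of viruses, by -0.36 ± 0.11. Over all genes 0 members passed. Camera gave an adjusted p of 1.7e-04, and an adjusted p = 0.389 with an estimated correlation. Without CCR2-negative replicate 2 the median was -0.14, with the preset call kept (adjusted p = 8.5e-04).

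Camera at the preset correlation also called the glycolysis, haematopoietic transcription factor and quiescence lists lower. They are not all separate from the lists above. The transcription factor list shares 2 genes with the stem cell identity list, Meis1 among them, and the quiescence list shares 1 with it. All 13 glycolysis genes were lower, with a median of -0.14. Pkm, which encodes pyruvate kinase, was 1.83-fold lower (-0.87 ± 0.19) and was the single member past the threshold when adjusted over the list alone, while Slc2a1, the glucose transporter GLUT1, differed by -0.34 ± 0.15, Pgam1 by -0.31 ± 0.14 and Hk2 by -0.25 ± 0.14. Of the transcription factors 18 of 27 were lower, with a median of -0.18. Hoxa9 differed by -0.67 ± 0.19, Meis1 by -0.64 ± 0.17, Etv6 by -0.51 ± 0.12, Lmo2 by -0.45 ± 0.13 and the corepressor Cbfa2t3 by -0.31 ± 0.16. None of them passed when adjusted over the list alone. Of the quiescence genes 11 of 16 were lower, with a median of -0.09. Cdkn1b, the cell cycle inhibitor p27, differed by -0.42 ± 0.12 and Txnip, an inhibitor of thioredoxin, by -0.50 ± 0.14, and both passed over the list alone. Rb1, the retinoblastoma protein gene, passed in the other direction (0.59 ± 0.17), but the mean of its probe sets gave -0.26. Over all genes 0 members of the 3 lists passed. Camera gave adjusted p-values of 0.0037, 0.0074 and 0.0439 for the 3 lists, and adjusted p = 0.389, 0.389 and 0.397 with an estimated correlation. The quiescence median lay at percentile 18.7 and the glycolysis median at percentile 4.48 of random lists matched on mean level, both inside the central 95%. The transcription factor call was lost without CCR2-negative replicate 1 (median -0.11, adjusted p = 0.0749), without the probe sets under the median level (adjusted p = 0.107) and with cyclic loess (adjusted p = 0.0660). The glycolysis call was lost without the probe sets under the median level (adjusted p = 0.0517). The glycolysis median was -0.23 without CCR2-positive replicate 1, -0.09 without CCR2-positive replicate 3 and -0.09 after a second quantile normalization, with the preset call kept. The quiescence call was lost without CCR2-negative replicate 1 or 3 or CCR2-positive replicate 1 or 3 (medians -0.05, -0.13, -0.04 and -0.09, adjusted p = 0.178, 0.0537, 0.0987 and 0.102). It was kept without CCR2-negative replicate 2 or CCR2-positive replicate 2 (medians -0.15 and -0.14). It was also lost with either filter on dim probe sets (adjusted p = 0.0886 and 0.266), a second quantile normalization (median -0.05, adjusted p = 0.132) and cyclic loess (adjusted p = 0.165).

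**Figure D3:**
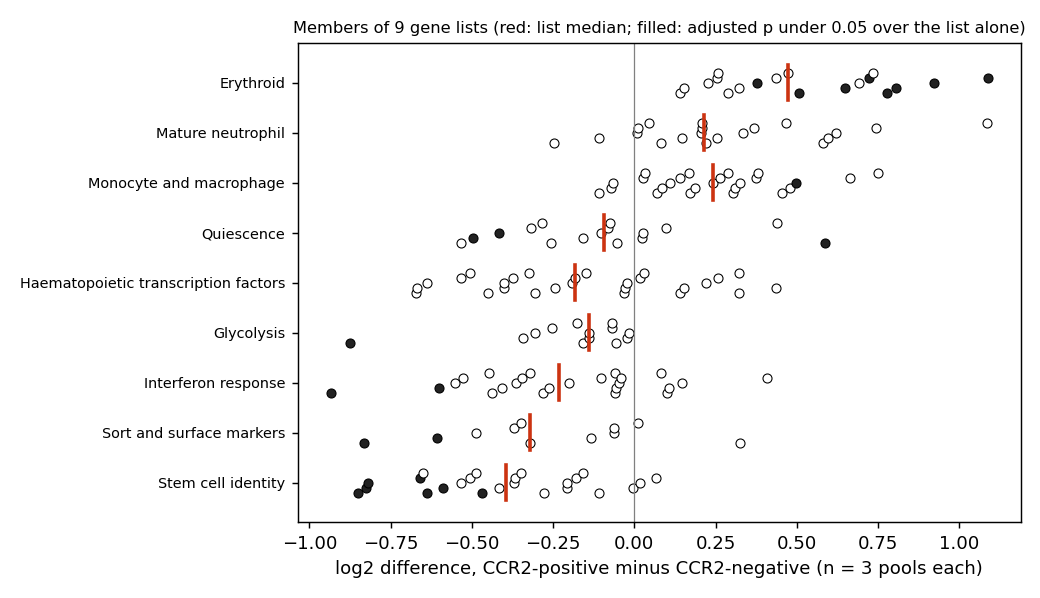
Log2 difference of each measured member of the 9 lists called by camera at the preset correlation, CCR2-positive minus CCR2-negative (n = 3 pools each). Red lines are list medians, 0.47 for erythroid and -0.39 for stem cell identity genes, and filled points passed an adjusted p of 0.05 over their list alone.

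Cell cycle genes did not pass as lists. S phase genes had a median of 0.07 (22 of 31 higher, camera adjusted p = 0.176), and G2 and M phase genes had a median of -0.07 (23 of 34 lower, adjusted p = 0.104). Ccne1, which encodes cyclin E1, differed by 0.46 ± 0.12, Cdc6, a replication licensing gene, by 0.60 ± 0.20 and Rrm2, a subunit of ribonucleotide reductase, by 0.39 ± 0.12. The kinetochore gene Ndc80 differed by -0.63 ± 0.26. Neither list had a member past the threshold when adjusted over the list alone. At the preset correlation S phase was called higher with all pools after a second quantile normalization (median 0.12, adjusted p = 0.0167), with cyclic loess (median 0.11, adjusted p = 0.0055) and without the probe sets under the median level (adjusted p = 0.0330). It was also called higher without CCR2-positive replicate 3 (median 0.19, adjusted p = 6.3e-04), but its median turned to -0.018 without CCR2-positive replicate 2 (adjusted p = 0.716). With an estimated correlation neither list passed (adjusted p = 0.775 for both). G2 and M phase was called lower without CCR2-negative replicate 1 (median -0.13, adjusted p = 0.0035) or CCR2-positive replicate 2 (median -0.16, adjusted p = 5.0e-04), and by camera on ranks (adjusted p = 0.0408). Its median turned to 0.0077 without CCR2-negative replicate 2 and 0.0018 without CCR2-positive replicate 3 (adjusted p = 0.750 and 0.837).

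The granulocyte-monocyte progenitor and lymphoid priming lists did not pass, with camera adjusted p-values of 0.609 and 0.418. The progenitor median was 0.031 with all pools and from -0.219 (without CCR2-positive replicate 2) to 0.080 with 1 left out, and the lymphoid median was 0.015 and from -0.058 to 0.045. Among progenitor genes Fcgr3, an Fc receptor gene, differed by 0.50 ± 0.13 and Csf3r, the receptor of G-CSF, by -0.43 ± 0.11, and both passed over the list alone in opposite directions. In the lymphoid list Cd27 was the single member to pass over the list alone. Of the megakaryocyte and platelet genes 11 of 20 were lower (adjusted p = 0.418), with a median from -0.084 to 0.072 as each pool was left out, and Selp, which encodes P-selectin (-0.66 ± 0.13), and Trpc6, a cation channel gene (-0.87 ± 0.21), passed over the list alone. Of the innate sensing and NF-kB genes 16 of 27 were lower (adjusted p = 0.115). Its members Tnfrsf1a and Tnfrsf1b, the receptors of TNF, differed by -0.52 ± 0.12 and -0.50 ± 0.13, and Casp1, the inflammasome protease, by -0.71 ± 0.19. These 3 passed over the list alone, and the list was called lower without CCR2-negative replicate 1 (median -0.08, adjusted p = 0.0400) and with array weights on all pools (adjusted p = 0.0449). It did not pass with an estimated correlation (adjusted p = 0.389), and its median was -0.038 with all pools and -0.0082 without CCR2-negative replicate 3 (adjusted p = 0.331).

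Markers of the remaining cell types did not pass as lists. The basophil, mast cell and eosinophil list had a median of 0.12 (adjusted p = 0.263) and was called higher without CCR2-positive replicate 1 (median 0.20, adjusted p = 0.0085). Its median was 0.055 without CCR2-positive replicate 2 and 0.068 without CCR2-negative replicate 3 (adjusted p = 0.723 and 0.501), and with an estimated correlation its adjusted p was 0.691. Mcpt8, the basophil protease, was 5.96, 8.76 and 9.09 in the 3 CCR2-positive pools and 6.22 ± 0.29 (SD, n = 3) in the CCR2-negative pools. The B cell list had a median of 0.12 (adjusted p = 0.0683) and was called higher without CCR2-negative replicate 3 or CCR2-positive replicate 1 (medians 0.16 and 0.13, adjusted p = 0.0481 and 0.0301), with the mean of a gene's probe sets (adjusted p = 0.0471) and by camera on ranks (adjusted p = 0.0441). Its median was 0.064 without CCR2-positive replicate 3, and with an estimated correlation its adjusted p was 0.410. In the endothelial list (adjusted p = 0.423) Tek and Emcn, which encodes endomucin (-0.92 ± 0.20), and, in the other direction, Plvap (0.48 ± 0.13) and Ptprb (0.37 ± 0.11) passed over the list alone. In the stromal list (adjusted p = 0.380) Col1a2, a collagen gene, differed by -0.45 ± 0.11 and passed over the list alone. Dendritic cell and MHC class II genes had an adjusted p of 0.233, T and NK cell genes 0.606 and innate lymphoid genes 0.943. Migration and adhesion genes had an adjusted p of 0.316, and immediate early and stress genes 0.423. Ribosomal protein genes had an adjusted p of 0.418. Oxidative phosphorylation genes (0.793) were called higher without CCR2-negative replicate 2 (median 0.10, adjusted p = 0.0109), and ribosome biogenesis genes (0.360) without CCR2-positive replicate 3 (median 0.18, adjusted p = 0.0013) and with cyclic loess (median 0.12, adjusted p = 0.0422). The first median turned to -0.053 without CCR2-negative replicate 1, -0.018 without CCR2-negative replicate 3 and -0.019 without CCR2-positive replicate 2, and the second to -0.038 without CCR2-positive replicate 2. With an estimated correlation neither passed (adjusted p = 0.967 and 0.847). Basophil, B cell, dendritic, T and NK cell, innate lymphoid, migration, immediate early, ribosomal, oxidative phosphorylation and ribosome biogenesis genes had no member past the threshold over their list alone, and no member of any list passed over all genes. Xist was 11.15 ± 0.05 (SD, n = 3) in CCR2-positive and 11.19 ± 0.18 (SD, n = 3) in CCR2-negative pools. The Y-linked genes Kdm5d, Uty and Eif2s3y lay between 3.75 and 4.18 in group means, and 0 of the 4 passed over the list alone. At that low level Kdm5d still differed by 0.27 ± 0.11.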

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

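Cyclic loess was chosen after seeing the data, and the other alternatives were planned. No gene passed the threshold in limma in any alternative but 1: leaving out each pool in turn gave 0 to 2 genes, and the 2 genes appeared without CCR2-positive replicate 1, where Mcpt8 (2.70 ± 0.19, adjusted p = 0.0222) and Gca (-1.55 ± 0.13, adjusted p = 0.0290) passed. Without that pool the CCR2-positive group held only the pools with high Mcpt8. On all probe sets 0 passed under each alternative run. The number of genes at an unadjusted p under 0.05 was 1921 to 3035 with 1 pool left out. It was 1704 without the probe sets under the median level, where 12394 genes were tested. Of the genes at that p, 30.7% were higher without those probe sets, against 46.0% with all, 38.8% with median centring and 54.4% after a second quantile normalization. Camera called 8 to 10 lists with 1 pool left out, 0 lists with the correlation estimated per list (1 list at an unadjusted p under 0.05) and 0 lists with fry (4 at an unadjusted p under 0.05). Called lists kept their direction in all 14 refits that could change a camera result, which the eBayes options cannot. Erythroid, stem cell identity, surface marker and interferon genes kept their call in all 14. Quiescence kept it in 5, transcription factors in 11, and glycolysis, neutrophil and monocyte genes in 13 each. All 14 refits used camera at the preset correlation, so a kept call does not test that setting. Some splits of the pools that mix the sorts gave as many preset calls, as given below. Of the 18 lists not called, 11 had a median that turned in sign with 1 pool left out. Camera on ranks called 11 lists, with the G2 and M phase and B cell lists added. With all pools, S phase was called under 3 refits, and the B cell, innate sensing and ribosome biogenesis lists under 1 each. In the lymphoid priming, granulocyte-monocyte progenitor and endothelial lists, none of them called, the median (0.015, 0.031 and 0.0016) and the mean difference (-0.07, -0.01 and -0.11) had opposite signs. The Ccr2 difference was 0.59 to 1.05 and its adjusted p 0.123 to 0.572 over 15 alternatives. With the replicate number as a block, 0 genes passed in limma (smallest adjusted p = 0.0618) and 2935 genes had an unadjusted p under 0.05. The quiescence call was lost under the block (camera adjusted p = 0.0669) while no other list call changed. The direction turned for 4 named genes, none past the threshold over all genes. Flt3 turned to -0.0126 with median centring and -0.0121 with cyclic loess, with a range of -0.0772 to 0.0973 as each pool was left out. Itga2b turned to 0.0077 with a second quantile normalization, with a range of -0.173 to 0.0574, Xist had a range of -0.142 to 0.0118, and Rb1 turned to -0.256 with the mean of its probe sets. The cause of these turns was not tested. Low signal could not be weighed beyond the filters, because no detection calls were used here.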

Other observations

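Of the tests in this part, those of a single pool and of a lower share of stem cells were chosen after the result was seen, and the 3 patterns weighed were picked once the list results were known. Genes outside the lists are named here after their values were seen. At an unadjusted p under 0.05, 9 genes were at least 2-fold higher and 40 at least 2-fold lower in CCR2-positive pools, none past the adjusted threshold. Small RNA entries, which make up 2.56% of the genes tested, were 5 of the higher and 11 of the lower ones. Slpi, which encodes a protease inhibitor of the secretory leukocyte type, was 2.08-fold higher (1.05 ± 0.23, adjusted p = 0.183). Among the lower genes were the cytokine genes Il18 (-1.38 ± 0.31) and Il15 (-1.06 ± 0.22), the inflammatory caspase gene Casp4 (-1.04 ± 0.34), Anxa1, which encodes annexin A1 (-1.09 ± 0.20), and the transcription factor genes Tfec (-1.24 ± 0.29) and Maf (-1.25 ± 0.34). Bex2 (-1.58 ± 0.24) and Myl10 (-1.57 ± 0.27) had larger differences. Of these named genes, Casp4 and Maf had pools that overlapped between the groups.

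The Hox genes are named after their values were seen as well. In clusters A and B, 7 of 19 measured genes were lower at an unadjusted p under 0.05 and 1 was higher. In clusters C and D, 0 of 17 were lower and 4 higher. Hoxb6 differed by -0.55 ± 0.10, Hoxa7 by -0.46 ± 0.10 and Hoxa5 by -0.52 ± 0.15, while Hoxc6 differed by 0.42 ± 0.17. All 17 genes of clusters C and D, and 12 of the 19 of A and B, lay in the lower 3 of 5 equal groups by mean level, where the medians of all genes were 0.046, 0.084 and 0.061. No Hox gene passed the adjusted threshold, and a difference between the clusters was not tested.

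The 6 pools can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2716 genes at an unadjusted p under 0.05 and the highest of the others 1133, so that 1 of the 10 splits gave as many. For genes and for probe sets past the adjusted threshold, 10 of 10 splits gave as many, since all gave 0. Camera at the preset correlation called 9 lists in the real split, and 5 of the 10 splits, the real one included, gave as many, with up to 11 in another. Splits that mix the sorts thus gave as many calls, so a preset call by itself cannot be put down to the sort. Against random lists matched on mean level, the S phase and ribosome biogenesis medians, not called on all genes as deposited, lay at percentiles 99.95 and 99.8. Those of the called surface marker, transcription factor and interferon lists lay at 0.06, 0.09 and 0. Random lists lack the correlation between members, estimated at 0.357 for S phase and 0.624 for ribosome biogenesis, so these percentiles are no measure of chance. The S phase and ribosome biogenesis medians turned to -0.018 and -0.038 without CCR2-positive replicate 2. The called quiescence and glycolysis lists lay inside the central 95%, at 18.7 and 4.48. The mean difference of the erythroid list was 0.517 in the real split and at most 0.413 in another, and that of the stem cell identity list was 0.400 in size against at most 0.372. Both lists were picked once the results of the real split were known, so its first rank is no separate test. The next largest values came from splits that put CCR2-positive replicate 3 among CCR2-negative pools.

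The erythroid median lay at percentile 100 of 10000 random lists matched on mean level, whose own median was -0.04, so that a trend with brightness runs against the higher erythroid values and this test could not have favoured it. No single pool alone accounts for the higher erythroid values. The median was 0.353 to 0.619 as each pool was left out, lowest without CCR2-positive replicate 2. Leaving out 1 pool cannot weigh 2 pools at opposite ends. The list mean of CCR2-negative replicate 1 lay at -0.52 and that of CCR2-positive replicate 2 at 0.53 from the mean over all pools. Erythroblasts among the sorted cells stay open: late erythroid genes (mean 8.08 against 7.55) were higher by 0.0328 more than early ones (9.39 against 8.89), with a 95% interval of -0.06 to 0.12. An erythroid expression state of CCR2-positive stem cells also stays open, as untested, and 3 of the 19 genes are in another list.

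Lower stem cell identity genes lay at percentile 0 of random lists matched on mean level (central 95% from -0.17 to 0.05), though that range ignores correlation between members. The random lists had a median of -0.06, far from -0.39, which argues against a trend with brightness as the whole of it. In that trend the dimmest of 5 equal groups of genes had a median of 0.05 and the brightest of -0.05. These were 0.019 and 0.00094 without CCR2-positive replicate 3, and 0.057 and -0.11 without CCR2-positive replicate 2. The size rests in part on 1 pool, with a median of -0.243 without CCR2-positive replicate 2 against -0.39 with it. A lower share of stem cells in the CCR2-positive pools stays open. The test of it asked whether the genes of other cell types rose alike. A lower share need not bring that where a single cell type takes the place of stem cells, so the test cannot decide. The erythroid list was higher by 0.548 more than the mean of the granulocyte-monocyte, lymphoid and megakaryocyte lists, with a 95% interval of 0.05 to 1.04. The interval held 0 in 5 of 6 cases with a pool left out, and stem cells express some genes of those lists. More erythroid-type cells in place of stem cells would be such a lower share. A stem cell state that goes with CCR2 may also account for the lower stem cell identity genes.

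Monocyte and neutrophil genes lay at percentile 100 of random lists matched on brightness. Their joint median was 0.219 with all pools and 0.125 without CCR2-positive replicate 2, so a large part may come from that pool. Mature myeloid cells among the sorted cells could not be told apart from myeloid expression in the stem cells. The 7 abundant mature genes were higher by 0.241 more than the other 38, with a 95% interval of -0.53 to 1.01 that is too wide to decide. Among the abundant genes, S100a8 had means of 7.87 and 6.79, CCR2-positive first, with a difference of 1.08 ± 0.96 that is about the size of its error. Lyz2 had means of 9.63 and 9.60 (0.03 ± 0.13).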
